A study of Eptesicus fuscus and Canis lupus familiaris and Equus caballus with 4 samples.

How the data were processed

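Small RNA from adult testis of dog, horse and the big brown bat Eptesicus fuscus was sequenced as 50 bp single-end Illumina reads, per the labels' protocols. The series holds 4 libraries, and 3 of them were analysed here, 1 per species. The other bat library, from another individual, was not analysed here. Species were taken from the sample titles. With 1 library per species no test between species was run and no p-value is given.

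Each of the 3 lists holds hairpin candidates that the authors obtained with a local installation of miRanalyzer, a program that predicts miRNA hairpins from mapped small RNA reads with 5 models, per the deposited description of the columns. The deposited counts are whole numbers, namely the distinct read sequences and the summed reads at each candidate, and are not normalized. The deposited score is the number of the 5 models that predicted the candidate, and in these lists it is 4 or 5. The deposited fraction is the read count divided by all reads in the authors' analysis, given to 3 decimals. Each list also gives the hairpin and mature sequences and their positions, which were checked to be 1-based and to hold the mature sequence at its stated place. Dog positions are on CanFam3.1 per the submitters' processing notes. Those notes name the same dog build for the bat and the horse, so the bat build, whose contig names begin with ALEH, and the horse build are not given in the sources used here. Trimming, mapping settings and any removal of known miRNAs are also not given in the sources used here. No gene annotation of these builds was used, so no exon, intron or UTR is stated for a candidate.

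The total of reads in the authors' analysis was bounded from the counts and the rounded fractions. It lay between 98889 and 99340 reads for the bat, between 545429 and 549349 for the horse and between 507211 and 512667 for the dog. Whether this total was defined in the same way for the bat as for the other species was not settled here, so it is not read as depth. Candidates with an identical mature sequence carried the same read count in 65 of 68 such sets in the bat, 33 of 33 in the horse and 24 of 24 in the dog. Summed reads therefore count such reads more than once, and for groups, families, clusters and whole lists the sum with each identical mature sequence once is given too where it differs.

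Conserved miRNAs were found by comparing each mature sequence with a fixed list of 85 mature sequences from 72 families, allowing at most 2 mismatches over 18 bases and a start offset of at most 2 bases. The list was written from general knowledge of vertebrate miRNAs. It holds part of the known families, so a candidate without a match is not thereby unknown. Its families were grouped as testis and germ line, let-7, ubiquitous, smooth muscle and stroma, blood, endothelium, skeletal muscle, liver, neural and epithelium. Sequence families within a species were built with blastn 2.17.0 (word size 7, E-value 0.001), joining hairpins at different loci, which could be opposite strands of the same stretch, that aligned over at least 50 bases at 80% identity or more, and 1 base-shuffled copy of each hairpin served as background. Hairpins that overlapped on the same strand were merged into 1 locus. Mature sequences of each species pair were compared by the same rule as for conserved miRNAs, beside 100 shuffles of the sequences. Clustered loci were those within 10000 bases of another on the same chromosome or contig. Folding energies came from RNAfold 2.7.2, and the rest was computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

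Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat candidates or reads as independent. On simulated sequences the mature match found 200 of 200 sequences with up to 2 mismatches and 0 of 1000 random ones. The family step found 120 of 120 simulated members at 2% and 5% divergence from their ancestor and 119 of 120 at 8%. It placed 0 of 300 single hairpins in a family, and these were random sequences without a stem.

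The comparisons, their main settings, the conserved list and the naming rule were fixed before the data were examined. The rule named the 10 candidates with most reads per species, the 5 conserved candidates with most reads per species and 3 per group, the 5 largest sequence families per species and the mature sequences shared by all 3 species. Other settings fixed at that time were a minimum of 10 reads, all 5 models, identical mature sequences once, seed or exact matches, other identity and length limits for families, lists drawn down to 252 candidates, no top candidate, no conserved candidates and cluster distances of 3000 and 50000 bases. Merged loci, a minimum fraction of 0.001, counts without conserved candidates, conserved sequences anywhere in the hairpin, families without pairs at 95% identity or more, families without pairs on opposite strands of the same stretch, identical mature sequences once in read sums and all values for chromosome X were chosen after seeing the data.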

Results

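Hairpin candidates were listed from 1 testis small RNA library each of the big brown bat, the horse and the dog. A hairpin candidate is a stretch of genome whose transcript can fold back on itself and that has reads on an arm. Reads pile up there at a miRNA gene, but a candidate here could rest on 1 read. The candidates summed to 89091 reads in the bat, 61054 in the horse and 63429 in the dog, and to 78353, 49454 and 54563 reads when each identical mature sequence was counted once. These single-counted sums were 79.1% of all reads in the authors' analysis for the bat, 9.04% for the horse and 10.7% for the dog. Whether that total was defined alike for the 3 species is not given in the sources used here. There were no replicates in the comparison.

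The bat list was the longest. It held 762 candidates, against 439 in the horse and 252 in the dog, that is 1.74 times the horse number and 3.02 times the dog number. Candidates with at least 10 reads numbered 255, 124 and 98 in the same order, and those without a match to the conserved list numbered 667, 437 and 240. The order bat, horse, dog held for these counts and for merged loci, of which there were 669, 391 and 232. Among candidates without a match, 46 bat, 3 horse and 7 dog hairpins held a listed sequence somewhere in the hairpin, where it could still overlap the mature sequence. The series title asks how many putative miRNAs the bat has. These counts bear on that question only as lengths of lists, since any removal of known miRNAs is not given.

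Many candidates rested on few reads. The median was 3 reads in each species, and 30.2% of bat candidates (26.9 to 33.6), 35.5% of horse candidates (31.1 to 40.2) and 34.9% of dog candidates (29.1 to 41.2) rested on 1 read. All 5 models predicted 393 bat, 207 horse and 126 dog candidates.

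**Figure D1:**
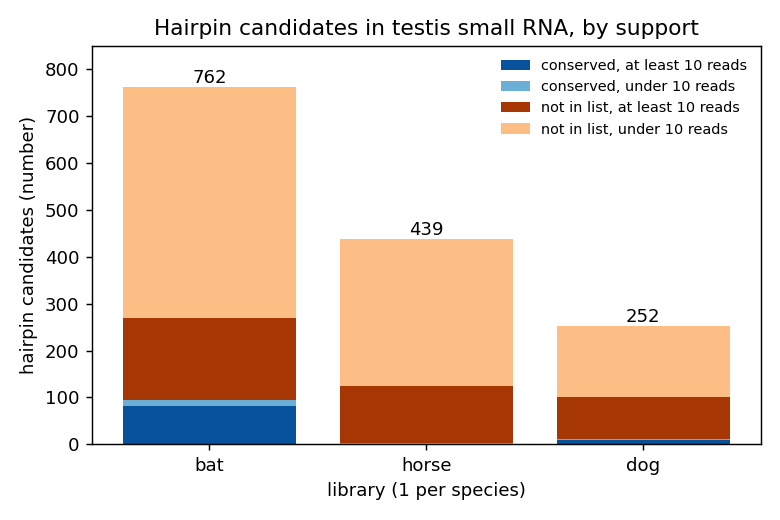
Number of hairpin candidates (vertical axis) in the single library of each species, with bars split by a match to the conserved list and by support of at least 10 reads. The bars reach 762 in the bat, 439 in the horse and 252 in the dog, and most of each bar is candidates under 10 reads without a match.

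The 10 candidates with most reads differed in kind between the species. In the bat, 5 of the 10 matched conserved miRNAs. The top candidate, Candidate_602 at ALEH01139364.1, 1202 to 1346 on the plus strand, had 9487 reads, the mature sequence TCTCTAGTTGTAGGACGTCCATTCA and no match. It was followed by miR-99a-5p with 8100 reads, miR-22-3p with 4975, miR-145-5p with 3276 and miR-101-3p with 2811. The other places went to miR-125b-5p with 2341 reads and to 4 copies of a related hairpin. Of these copies, Candidate_97 and Candidate_493 each listed 2451 reads of TTGGCTGCATCACTGGTACTGATGT, and Candidate_155 and Candidate_909 each listed 2198 reads of TTGGCTGCATCACTGGTACTGAGGT.

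In the horse, 7 of the 10 lay on chromosome X and none matched the conserved list. Candidate_640 led with 11811 reads of CTACCCGGAAGGTACTGATCACCTA, at X, 115867008 to 115867102 on the minus strand, and Candidate_634 followed with 7855 reads of TGAATGGCACCTTTCTGAGTAGAGT at X, 116755599 to 116755743. Candidate_598 and Candidate_616 shared TAGTCGGTGCCATCTGGGTAGAGC with 3160 reads each. Candidate_603, Candidate_617 and Candidate_651 shared TACCCAGCAAGGTACTGATCGCTTA with 3154 reads each. Off chromosome X, Candidate_171 on chromosome 22 had 5727 reads, its overlapping neighbour Candidate_184 had 1898 and Candidate_2 on chromosome 20 had 2922.

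In the dog, miR-486-5p, a miRNA abundant in red blood cells and muscle, dominated. Candidate_165 on chromosome 16, 23958924 to 23959066 on the minus strand, carried 37280 reads of TCCTGTACTGAGCTGCCCCGAGCT, which was 58.8% of the listed dog reads. Candidate_353 on the unplaced scaffold Un_JH373668 followed with 5968 reads, and Candidate_357 on the same scaffold had 985. Candidate_318, Candidate_327, Candidate_332 and Candidate_338, all within X, 114680869 to 114689915, each listed 1546 reads of TAATTAGGACCTCCCTGAGCGGAGT. Candidate_334, also on chromosome X, had 1030 reads, and the last places went to Candidate_49 and Candidate_237, which shared miR-199a-5p with 984 reads each.

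Conserved miRNAs were common in the bat list and rare in the other lists. Any removal of known miRNAs is not given, so this compares the lists and not the miRNAs of the species. Of the bat candidates, 95 (12.5%, 10.2 to 15.0) matched the conserved list and covered 52 families. In the dog 12 candidates (4.76%, 2.48 to 8.17) matched 8 families, and in the horse 2 candidates (0.456%, 0.0552 to 1.64) matched 2 families. Among candidates with at least 10 reads the shares were 31.8% in the bat, 9.18% in the dog and 0.806% in the horse. Bat conserved candidates were well supported, with a median of 195 reads against 2 for the others.

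Ubiquitous miRNAs made up most of the bat matches, with 30 of the 38 listed families and 32435 reads, or 31972 with identical sequences once. Besides miR-99a, miR-22 and miR-101 they included miR-125b and miR-26a, the latter with 891 reads at its best candidate. MiR-99a-5p lay at ALEH01062116.1, 4037 to 4171, and the best let-7 candidate, with 1037 reads, lay on the same contig at 4759 to 4903. Let-7 miRNAs, linked to differentiation, had 4 bat candidates and 1328 reads.

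Of the 11 testis and germ line families, 6 were matched in the bat, with 4067 reads over 12 candidates. The best supported were miR-19b-3p with 1352 reads, miR-25-3p with 809 and miR-93-5p with 477, members of the miR-17 cluster and its relatives, which act in cell proliferation. MiR-449a, of the miR-34 and miR-449 family active in spermatogenesis and ciliated cells, had 414 reads in the bat. A horse match to this family, Candidate_149 on chromosome 21, 17151814 to 17151938, had 218 reads. Its closest listed entry was miR-449a, but its sequence differed from the bat one at 2 bases. The other horse match was miR-372-3p with 4 reads. The dog list held no match to this group.

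Markers of other cell types were also in the lists. Smooth muscle and stroma miRNAs had 4729 bat reads, or 3973 with identical sequences once, led by miR-145-5p with 3276, miR-199a-3p with 256 and miR-199a-5p with 244 at their best candidates. In the dog this group was miR-199a-5p alone, with 2513 reads over 3 candidates, or 1529 with the identical pair once. Blood miRNAs had 570 bat reads, of which 549 were miR-486-5p at Candidate_459 and Candidate_460, with 276 and 273 reads on opposite strands of 1 stretch. With that stretch once the sum was 297, miR-142-3p had 18 reads and miR-223-3p had 3 at their best candidates, and the dog had 37280 reads from miR-486-5p. Epithelial miRNAs had 592 bat reads, led by miR-141-3p with 388, miR-200b-3p with 117 and miR-205-5p with 67.

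Neural miRNAs had 612 bat reads, 585 of them from 3 copies of miR-9-5p and 27 from 3 copies of miR-124-3p, and 204 with identical sequences once. Skeletal muscle miRNAs had 176, or 98 with identical sequences once, with miR-133a-3p at 52 and miR-1-3p at 26 reads for their best candidates. The endothelial miR-126-3p had 132 reads in the bat, and the liver miRNA of the list was not matched in any species. In the dog, let-7 had 91 reads over 2 candidates, the best at 72, and the ubiquitous group had 93, or 90 with identical sequences once, led by miR-146a-5p with 64, miR-186-5p with 11 and miR-30a-5p with 10.

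Conserved miRNAs carried large shares of the listed reads in the bat and the dog. The share was 50.1% in the bat (49.8 to 50.4), 63.0% in the dog (62.6 to 63.4) and 0.364% in the horse (0.317 to 0.415). The dog share rested on miR-486-5p, and without that candidate it was 10.3%. Without its own top candidate the bat share was 56.1%. With identical sequences once the shares were 54.8% in the bat, 71.5% in the dog and 0.449% in the horse.

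Families of similar hairpins, in which opposite strands of the same stretch also counted as different loci, held 383 of the bat candidates (50.3%, 46.7 to 53.9), 91 of the dog candidates (36.1%, 30.2 to 42.4) and 24.4% of the horse candidates (20.4 to 28.7). Without pairs on opposite strands of 1 stretch, which involved 17 bat, 3 dog and 2 horse candidates, the shares were 48.8%, 34.9% and 23.9%, each inside the interval above. No shuffled hairpin fell into a family, but shuffling bases also breaks up stems and simple repeats, so this background is a weak one. The order depended on the limits. At 90% identity the shares were 24.02% in the bat, 30.6% in the dog and 21.9% in the horse, and among candidates with at least 10 reads they were 32.9%, 46.9% and 38.7%. The title asks whether putative miRNAs arose from DNA transposons, and these shares do not test that origin.

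In these lists bat family members differed more from each other than dog and horse members did. The nearest member was 80 to 90% identical for 26.2% of bat candidates (23.1 to 29.5), 5.56% of dog candidates (3.07 to 9.15) and 2.51% of horse candidates (1.26 to 4.44). It was at least 95% identical for 11.02% of bat candidates (8.89 to 13.5), 27.8% of dog candidates (22.3 to 33.8) and 19.8% of horse candidates (16.2 to 23.9), counting opposite strands of 1 stretch, and for 8.92% (6.996 to 11.2), 26.6% (21.2 to 32.5) and 19.4% (15.8 to 23.4) without them. Some near-identical copies lay on unplaced sequence, such as 4 of the 6 members of the horse family led by Candidate_28, and Candidate_24 and Candidate_25 in the dog. All 41 candidates of the largest horse family lay on chromosome X. Whether copies repeat 1 stretch within an assembly was not tested, so the contrast may in part reflect the assemblies. Family members had a median of 2 reads in the bat, where other candidates had 6. In the dog members had a median of 12 reads and others 2, or 14 and 2.5 without opposite strands, and in the horse 7 and 2.

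**Figure D2:**
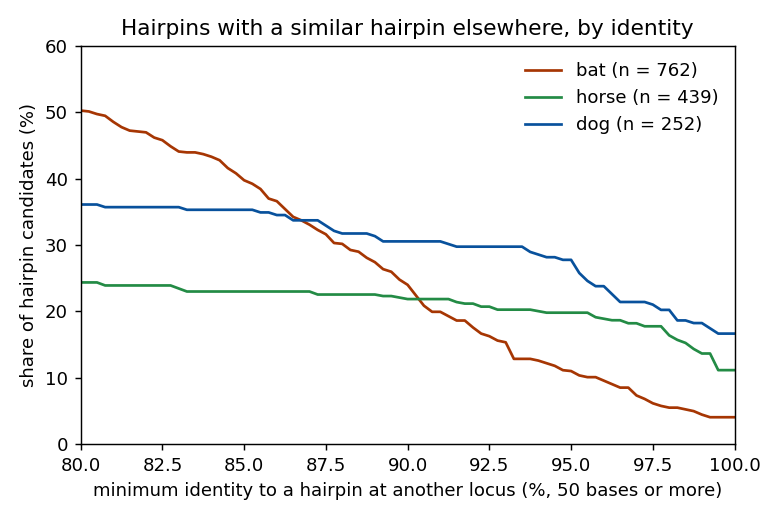
Share of hairpin candidates (percent) that have a similar hairpin at another locus or on the opposite strand, against the minimum identity asked for over 50 bases or more, 1 line per species. The bat line falls from 50.3% at 80% identity to 24.02% at 90%, and the dog line falls from 36.1% to 30.6%.

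The largest bat family had 97 loci, or 94 with opposite strands merged, on 94 contigs and 154 reads in all, or 102 with identical sequences once, and 68 of its members rested on 1 read. Its best member was Candidate_82 at ALEH01051799.1, 11921 to 12037, with 5 reads of TTCCGGGATGTGTCACCTGAG. The next had 47 loci on 47 contigs and 701 reads, or 699 with identical sequences once, of which Candidate_347 at ALEH01034351.1 gave 386. Among the 5 largest, a family of 33 loci was the strongly read one. It had 15831 reads over 49 candidates, or 7306 with identical sequences once, led by Candidate_97 at ALEH01124406.1, 1840 to 1984. Outside the 5 largest, the top candidate Candidate_602 led a family of 5 loci with 11343 reads, 9487 of them its own. The remaining families among the largest 5 had 14 loci with 21 reads, led by Candidate_20, and 10 loci with 10 reads, led by Candidate_92. With identical sequences once these came to 14 and 4 reads.

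The largest horse family lay wholly on chromosome X. It had 27 loci, 41 candidates and 31741 reads, or 20804 with identical sequences once, led by Candidate_640. The other 4 horse families had 6, 6, 3 and 3 loci, led by Candidate_28, Candidate_68, Candidate_26 and Candidate_29, with 42, 18, 129 and 18 reads. In each of these 4 the members listed 1 identical sequence, which counted once gave 7, 3, 43 and 6 reads. The largest dog families had 10 loci with 74 reads, led by Candidate_97 on chromosome 29, then 7 loci with 7 reads, 6 loci with 600 reads and 5 loci with 5 reads, led by Candidate_190, Candidate_24 and Candidate_25. With identical sequences once these 4 dog families came to 73, 1, 100 and 1 reads. The dog family of 4 loci led by Candidate_318 lay on chromosome X and had 6787 reads, or 1777 with identical sequences once.

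Few mature sequences were shared between the lists. Of the 38 ubiquitous families, 30 were matched in the bat list, 0 in the horse list and 5 in the dog list. Any removal of known miRNAs is not given, so these counts do not measure how far testis miRNAs differ between species. Of 647 distinct bat sequences, 15 (2.32%, 1.30 to 3.80) had a match in the horse and 22 (3.40%, 2.14 to 5.10) in the dog, and of 385 horse sequences 16 (4.16%, 2.39 to 6.66) had a match in the dog. Shuffled sequences gave a mean of 0.03 matches for each bat comparison and 0 for horse and dog. Of the 22 bat and dog matches, 11 matched the conserved list, against 1 of the 15 bat and horse matches. That list is partial, so the rest may also include known miRNAs. Of the 16 horse and dog matches, 10 lay on chromosome X in both species, and 6 of these 10 matched the single dog Candidate_339, which had 1 read. Counted from the dog, 5 of 11 matched sequences lay on X in both. With an identical seed in place of the longer match, the bat share in the horse was 6.49%, and with no mismatch it was 0.773%.

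Sequences shared by all 3 species numbered 4. None matched the conserved list, but that list is partial, so they are not thereby unknown. The bat sequence CAGATATTGCACGGTTGATCTCTT had 63 reads at ALEH01112080.1, 2897 to 3039, 543 reads on horse chromosome 24, 42908032 to 42908174, and 9 reads on dog chromosome 8, 69267134 to 69267274. TCGACCGGACCTCGACCGGCTCGT had 40 bat reads, with matches of 296 reads on horse chromosome 1 and 36 on dog chromosome 28. ATTGGCACTCTTTTGAGTGTGG had 151 bat reads at ALEH01144124.1, 2988 to 3126, and its matches on chromosome X had 27 reads in the horse and 8 in the dog. ACGCCCTTCCCCCCCTTCTTCA had 2 bat, 24 horse and 16 dog reads.

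Listed bat mature sequences were more often 20 to 24 bases long. Conserved matches did not raise this share, which was 81.9% in the bat without them. A length of 20 to 24 bases was found for 78.6% of bat candidates (75.5 to 81.5), 58.8% of horse candidates (54.0 to 63.4) and 57.1% of dog candidates (50.8 to 63.3). No listed mature sequence was longer than 25 bases, and 18.8% of bat, 39.4% of horse and 41.7% of dog sequences had that length. The first base was U in 47.2% of bat (43.7 to 50.9), 59.2% of horse (54.5 to 63.9) and 66.3% of dog sequences (60.1 to 72.1). Sequences of 25 bases began with U in 53.8% of bat, 74.6% of horse and 75.2% of dog cases. Among shorter ones the shares were 45.7% in the bat (41.7 to 49.7), 49.2% in the horse (43.1 to 55.4) and 59.9% in the dog (51.5 to 67.8), so bat and horse then overlapped. Hairpin GC content had medians of 55.5% in the bat, 57.6% in the horse and 57.7% in the dog.

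Clustering within 10000 bases had overlapping intervals in the 3 species. It took in 138 of 669 bat loci (20.6%, 17.6 to 23.9), 69 of 391 horse loci (17.6%, 14.0 to 21.8) and 39 of 232 dog loci (16.8%, 12.2 to 22.3). With opposite strands of 1 stretch merged it took in 124 of 661, 68 of 390 and 37 of 231. The largest clusters of horse and dog lay on chromosome X. In the horse, 28 loci on the minus strand between 115854275 and 115885738 had 31744 reads, or 20807 with identical sequences once. In the dog, 10 loci on the minus strand between 114675824 and 114689915 had 8375 reads, or 3077 with identical sequences once. Bat candidates lay on 580 contigs without a chromosome, so clusters there end with the contig.

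The dog scaffold Un_JH373668 held a further cluster of 6 loci and 8883 reads. In the bat the largest clusters were 9 loci with 466 reads on ALEH01112080.1 and 6 loci with 87 reads on ALEH01112078.1. A cluster of 4 loci and 580 reads at ALEH01123613.1, 1595 to 2403, held conserved matches to miR-17, miR-18a, miR-20a and miR-92a, 4 members of the miR-17 cluster.

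**Figure D3:**
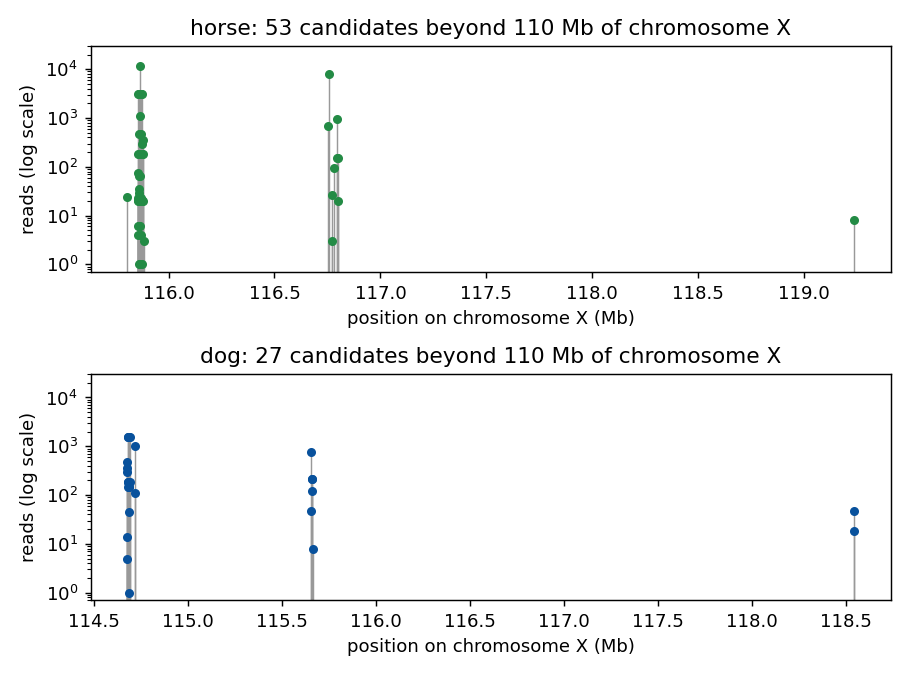
Reads per candidate (log scale) against position (Mb) for the 53 horse and 27 dog candidates beyond 110 Mb of chromosome X, 1 point per candidate. The horse points reach 11811 reads and the dog points 1546, and most lie in a few narrow groups.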

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

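Of 92 recomputed values, 48 stayed within 1.5 times a count or within the interval of a share, and 44 moved. The cause was not tested unless the setting itself removes candidates. In the order bat, horse and dog, candidates numbered 255, 124 and 98 with at least 10 reads, 393, 207 and 126 with all 5 models, and 113, 15 and 13 with at least 0.001 of all reads, a minimum that asks for fewer reads in the bat because its total is 0.194 times that of the dog and 0.181 times that of the horse. The bat conserved share was 9.71% by seed, 9.97% with no mismatch, 31.8% with at least 10 reads and 18.5% with the sequence anywhere in the hairpin. The dog conserved share was 9.18% with at least 10 reads.

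The family share was 24.02% in the bat at 90% identity. With 30 aligned bases it was 55.4% in the bat and 42.5% in the dog. With at least 10 reads it was 32.9% in the bat, 38.7% in the horse and 46.9% in the dog, so the bat then had the lowest share. Lists drawn down to 252 candidates gave 38.9% in the bat and 19.0% in the horse. With pairs at 95% identity or more not joined, the horse had 11.6% and the dog 15.5%, and with both changes the bat had 38.1% and the horse 10.7%. With pairs on opposite strands of 1 stretch not joined the shares stayed within their intervals, and the draws gave 38.5% in the bat and 19.0% in the horse.

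The conserved share of reads without the top candidate was 56.1% in the bat, 0.451% in the horse and 10.3% in the dog, and with identical sequences once 54.8%, 0.449% and 71.5%. The share of 20 to 24 bases was 81.9% in the bat without conserved candidates. Clustering within 50000 and 3000 bases was 24.3% and 11.0% in the horse and 23.3% and 11.2% in the dog. Bat sequences matched in the horse were 6.49% by seed and 0.773% with no mismatch, and horse sequences matched in the dog were 1.82% with no mismatch. The X share of reads with identical sequences once was 62.8% in the horse and 10.6% in the dog, and without the top candidate 61.3% and 43.2%. First base U and GC content stayed within their intervals without conserved candidates and with identical sequences once, but first base U fell outside them among sequences under 25 bases in the horse (49.2%) and the dog (59.9%). No paired analysis was possible because 1 library per species was analysed here. Candidates of 1 read made up 30.2% of the bat, 35.5% of the horse and 34.9% of the dog list.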

Other observations

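The draws of 252 candidates over all pairs were set before the data were examined, and all values for chromosome X and the other tests in this part were chosen after the results were seen, as were the limits applied to the draws. Candidates on chromosome X carried much of the listed signal in the horse, where 59 of 439 candidates held 68.8% of the reads (68.4 to 69.2). With identical sequences once that share was 62.8%. In the dog 36 of 252 candidates held 17.8% (17.5 to 18.1), or 10.6% with identical sequences once. Without miR-486-5p the dog share was 43.2%, with identical sequences counted at each copy. Support of at least 10 reads was found for 74.6% of horse X candidates (61.6 to 85.0) and 21.1% of the other horse candidates (17.1 to 25.5), and for 72.2% (54.8 to 85.8) and 33.3% (27.1 to 40.1) in the dog. No X candidate matched the conserved list. On the dog scaffold Un_JH373668, 4 of the 8 candidates had a mature sequence also listed on chromosome X.

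Bat relatives of the X candidates were present too. Of the bat mature sequences, 7 matched a horse or dog X candidate, led by Candidate_513 at ALEH01144127.1, with 872 reads of ATGTTTGGCACCTCTTTGAATGAA, and among them Candidate_514 on the same contig, with 331 reads of TGAAGTGCGCCTTCCTGAGTAGAG, and Candidate_869 at ALEH01144123.1, with 262 reads of TGATTGGCATCTCTTAAAGTGAGGT. Sequences of the miR-508, miR-509 and miR-514 group, at up to 5 mismatches over 18 bases, were held by 10 bat hairpins (1.31%, 0.631 to 2.40) on 9 contigs, which listed 3581 reads. The same search matched 1.58% of horse hairpins (0.582 to 3.41) and 0.463% of dog hairpins (0.0117 to 2.55) off chromosome X. The bat share lay inside both intervals and no shuffled background was run, so these 10 hairpins are not thereby members of the group. A further 4 bat sequences, on ALEH01112080.1 and ALEH01112078.1, matched horse candidates on chromosome 24. The horse Candidate_171 and Candidate_184, with 5727 and 1898 reads, had bat matches in Candidate_327 and Candidate_326 with 24 and 104 reads.

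A larger share of bat hairpins lay in sequence families at 80% identity, but not at 90% identity, where the dog had 30.6% and the bat 24.02%, nor with at least 10 reads, where the bat had the lowest share at 32.9%. List length may account for the excess over the dog. Draws of 252 bat candidates gave a median of 38.9% (32.9 to 45.2), under the dog's upper limit of 42.4%. The ranges of draws cover the drawing only, while the dog limits are Clopper-Pearson limits. List length did not account for the excess over the horse, whose draws gave 19.0% (15.5 to 23.8). Nor did it account for the excess over the dog in matches under 95% identity. With pairs at 95% identity or more not joined, the bat draws gave 38.1% (32.1 to 44.4) and the dog list 15.5% (11.2 to 20.5). Near-identical copies such as duplicated contigs stay open. Without those pairs the bat share was 48.4% (44.8 to 52.0), but near-identical candidates still counted where they had another match under 95%. A pair could also stay joined through a second alignment under 95%. Candidates whose nearest member was 80 to 90% identical are not such copies, and they made up 26.2% of the bat, 5.56% of the dog and 2.51% of the horse list. A search for 10 short repeat segments matched 29.2% of bat family members, but segments in it had been copied from these same hairpins, so the search was circular, a repeat origin stays open and no transposon is named.

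More conserved miRNAs stood in the bat list. The bat total of reads was 0.194 times that of the dog, but the total may be defined differently in the bat list, so a deeper bat library stays open. It also stays open whether known dog and horse miRNAs were counted in the total and left out of those lists. The horse list matched 0 of the 38 ubiquitous families and had 0 let-7 candidates. Listed reads, each mature sequence once, made up at most 10.7% of the total in dog and horse and 79.1% in the bat. The species difference itself stays open and untested, with 1 library each.

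Chromosome X held a large share of the listed reads in the horse, and a share in the dog that depended on miR-486-5p. Reads listed at several copies of an identical sequence were argued against in the horse, where the share was 62.8% with identical sequences once. They stayed open in the dog, where it was 10.6%. Reads listed at copies that differ by a few bases were not covered by this count and stay open. The largest horse family, on chromosome X, held 19 distinct mature sequences over 41 candidates. Relatives of miR-508, miR-509 and miR-514, X-linked testis miRNAs, may be among the X candidates. Of horse X hairpins 25.4% (15.0 to 38.4), and of the others 1.58% (0.582 to 3.41), held a sequence of the group at up to 5 mismatches over 18 bases. With each sequence family once, 5 of 13 and 6 of 314 did. In the dog 8.33% of X hairpins did (1.75 to 22.5), and 0.463% of the others (0.0117 to 2.55), with overlapping intervals, while with each family once 3 of 18 (3.58 to 41.4%) and 1 of 159 (0.0159 to 3.45%) did, the intervals apart, so the dog stays open. This resemblance had been noticed in a horse hairpin before the search.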
